A study of Mus musculus with 38 samples.

How the data were processed

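The data are 38 samples of mouse bone marrow-derived macrophages: 32 RNA libraries in 8 groups of 4, and 6 ChIP-seq libraries with 1 library per group (2 inputs, 2 of H3K18la and 2 of H3K18ac). Groups and replicate numbers were taken from the labels. The time of the lactic acid groups is read as the time after LPS and IFNg, as the labels' time field is named, and the labels give no dose of lactic acid. RNA was made into libraries with a stranded mRNA kit and chromatin was digested with micrococcal nuclease, per the labels' protocols.

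RNA values were deposited as RPKM, which the authors scaled by an effective size of each library. Per the labels, HISAT2 2.1.0, featureCounts 1.5.0-p1 and edgeR are among the tools named, with no role or order given. The same table holds the authors' log2 fold change of each group over 0 h, a mean log2 expression, and a p-value and FDR per gene. The deposited FDR was checked and lies within 0.85% of a Benjamini-Hochberg value over the listed genes. The deposited log2 fold changes differ from log2 ratios of the group means by a median of 7.1e-05 (99th percentile 0.0022) among genes with a mean log2 CPM above 5. The deposited spike-in table gives the count of reads in the mouse genome for each ChIP-seq library. For the H3K18la and H3K18ac libraries, but not for the inputs, it also gives the count in the spike-in and a factor written out by the authors. The peak lists hold for each peak the deposited fold enrichment, a ratio over the background of the caller. They also hold the deposited -log10 p and -log10 q and a deposited score, which is 10 times the -log10 q in every peak. MACS2 2.2.1, Bowtie2 2.2.6 and SAMtools 0.1.19 are named per the labels, with builds mm10 and GRCm38. The threshold and the control of the peak calls are not stated. The inputs have no peak list.

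The planned test for counts did not apply, because the table holds RPKM. Genes with at least 1 RPKM in at least 4 libraries were tested (9942 genes, while 1242 listed genes lay below). The test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1), with all 32 libraries in 1 model with a mean per group (24 residual degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 count as higher or lower. Log2 fold changes are on the log2(RPKM + 1) scale and understate changes of genes with low values. The authors listed only genes that pass their own test, with 19 exceptions at an FDR of 0.05 or more, so shares of genes called are shares of that list. There were 9 contrasts: 4, 8, 16 and 24 h against 0 h, 24 h against 4 h, lactic acid against none at 8, 16 and 24 h, and the difference between the effects of lactic acid at 24 h and 8 h.

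The whole reads behind the RPKM were recovered from the gene lengths and the effective library sizes: 99.82% of all values came out within 0.05 of a whole number, against 10.0% by chance, and 11158 genes came out whole in at least 30 of 32 libraries. Reads in listed genes per library ran from 61.3 to 69.6 M at 0 h, 87.0 to 103.9 M at 4 h, 74.0 to 79.6 M at 8 h, 76.3 to 92.8 M at 16 h and 62.7 to 78.2 M at 24 h. With lactic acid they ran from 71.2 to 102.5 M at 8 h, 61.5 to 88.9 M at 16 h and 60.6 to 94.5 M at 24 h. The effective size over the reads in listed genes averaged 1.334 at 0 h, 0.924 at 4 h, 0.955 at 8 h, 1.02 at 16 h and 0.956 at 24 h, and 1.016, 1.046 and 0.825 with lactic acid at 8, 16 and 24 h. This is why scaling to the reads in listed genes shifts all genes. Reads of Fth1, Saa3 and Lyz2 made up 4.422% of the total at 0 h and 15.48% at 24 h.

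The gene lists, 27 in all, were fixed before the data were examined: inflammatory (M1) mediators, interferon-stimulated genes, alternative (M2) activation markers, tissue repair and growth factors, glycolysis, lactate transport and handling, TCA cycle and pyruvate oxidation, respiratory chain, hypoxia (HIF) targets, histone acyl writers and erasers, cell cycle, cholesterol synthesis, LXR targets and lipid efflux, MHC class I presentation, MHC class II presentation, lysosome, NRF2 targets, unfolded protein response and heat shock, amino acid and integrated stress response, immediate early genes, mitochondrially encoded transcripts, and markers of macrophage identity, neutrophils and granulocyte precursors, dendritic cells, lymphocytes, erythroid and mast cells, and stromal and endothelial cells. They were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The adjustment ran over the lists of each contrast. For 8 h and 16 h against 0 h and for 24 h against 4 h no list test is reported.

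Genes were named by a rule fixed before the data were examined. It takes Nos2, Tnf, Il1b, Il6, Cxcl10, Arg1, Vegfa, Ldha and Actb always. It adds up to 3 called members of each list with the largest absolute log2 fold change. It also takes the 5 higher and 5 lower called genes with the largest absolute log2 fold change among genes with a mean of at least 3 log2 units, without unnamed gene models. For each mark it takes the 3 peaks with the highest fold enrichment in 1 state that no peak overlaps in the other. Some genes that the rule names are not reported here.

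Gene positions came from a RefSeq table of assembly GRCm38.p6, which pairs 11053 genes of the RNA table with a position (98.8%; 10827 by symbol and 226 by gene ID; 131 without). The table holds no strand, so a peak within 2 kb of either end of a gene took the place of the planned window around the transcription start. Overlaps of at least 1 bp were counted with bedtools 2.31.1 and set against 100 circular shifts. Gene length trends were removed, where stated, by subtracting a natural spline with 4 degrees of freedom on log2 gene length from each library. Figures were made with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

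The steps were tested on simulated data made for the comparison of LA 24h with 24h, with 10044 genes in the step. Of the genes planted at a fold change of 1.5, 59 of 67 were recovered (88.1%), at 2, 66 of 67 (98.5%), and at 4, 65 of 66 (98.5%), and 8 of 9844 unchanged genes were called. A set of 20 genes shifted by 0.3 on the log2 scale was called and 0 of 20 random sets were. Counts were drawn independently for each gene with the same dispersion, so no genes were correlated and no library stood apart. The simulation therefore cannot show how often the tests make false calls where genes are correlated or libraries stand apart. A planted length trend (Spearman rho 0.72) was at 0.00 after removal, and 400 of 400 planted overlaps among 1000 intervals were found.

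Alternatives fixed before the data were examined were no filter, a pseudocount of 0.1, a fit with only the groups compared, a replicate block, leaving out each library, a fold change of at least 2, other windows of 1 and 5 kb, a -log10 q of at least 5, at least 50% of a peak covered, and equal numbers of peaks. The planned median-of-ratios factors and DESeq2 test need counts, so they were run on the recovered reads (edgeR 4.0.16, DESeq2 1.42.0). Chosen after seeing the data were that use of the recovered reads, median-of-ratios scaling of the RPKM, scaling to the reads in listed genes, removal of the length trend (for list tests also with an estimated correlation), leaving out both libraries that stood apart at 24 h, and Fisher's exact test of lists against peak classes. Raw reads were not at hand, so no signal was measured outside the peak lists, and H3K18la levels at genes without a peak are unknown.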

Results

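Bone marrow-derived macrophages of C57BL/6 mice were profiled before stimulation (M0) and during polarization toward the inflammatory M1 state with lipopolysaccharide (LPS, 5 ng/ml) and interferon-gamma (IFNg, 12 ng/ml). RNA was sequenced at 0, 4, 8, 16 and 24 h. In a second arm, lactic acid was added 4 h after LPS and IFNg, and RNA was sequenced at 8, 16 and 24 h (called LA 8h, LA 16h and LA 24h here). Each of the 8 RNA groups held 4 libraries, 32 in all. Chromatin immunoprecipitation with sequencing (ChIP-seq) covered lactylation (H3K18la) and acetylation (H3K18ac) of the same lysine of histone H3, with spike-in chromatin, in M0 and in M1 after 24 h. There was 1 ChIP-seq library per mark and state and 1 input library per state, so no ChIP-seq value has a replicate.

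The RNA table gives RPKM (reads scaled by gene length and library size), and 9942 listed genes passed the expression minimum and were tested. The whole reads behind these values could be recovered, and the libraries held 60.6 to 103.9 M reads in listed genes. The first principal component of the RNA libraries took up 48.6% of the variance and the second 27.5%. On the second, 24h replicate 4 lay at 17.9 while the other 24h libraries lay at 8.7 to 11.6. LA 24h replicate 1 lay at 28.6 and the others of its group at 22.6 to 25.2. Expression also depended on gene length to a different degree in each library, as described with the lactic acid comparisons. The labels do not say whether replicates came from separate mice or cultures, so the limma p-values measure the spread between these libraries only. The p-values of camera set genes against other genes. Those of Fisher's exact test count genes, with peaks from 1 library per mark and state, and measure no spread between libraries.

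**Figure D1:**
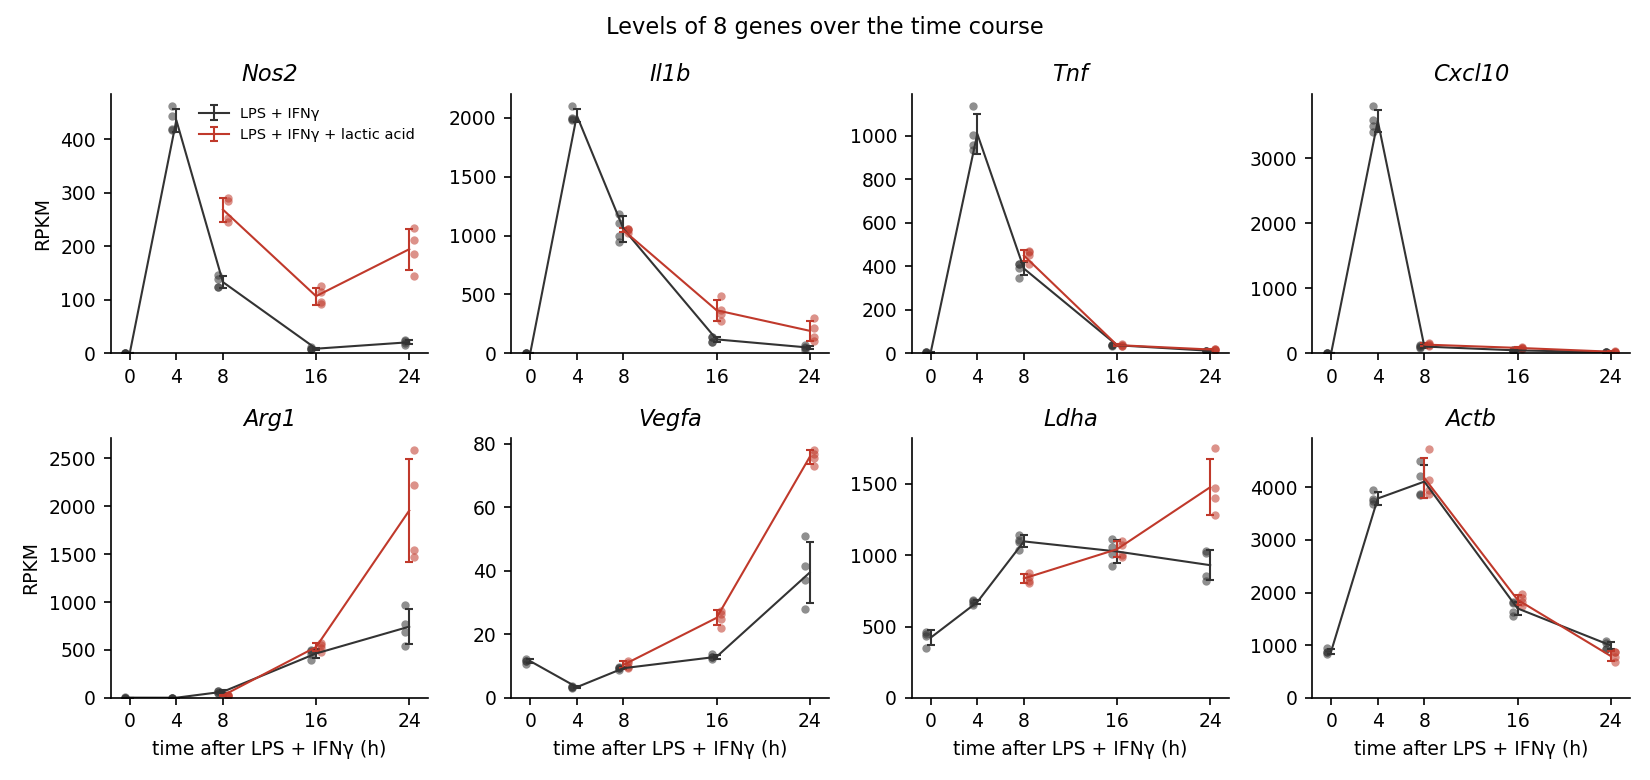
RPKM of 8 genes (vertical axis) against hours after LPS and IFNg (horizontal axis), without (black) and with (red) lactic acid; points are libraries, lines join group means and bars are SD (n = 4). Nos2 peaked at 435 RPKM at 4 h and was higher with lactic acid at 8, 16 and 24 h, while Arg1 reached 743 RPKM at 24 h without and 1955 RPKM with lactic acid.

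The comparison of 4 h with 0 h asks what the first hours of LPS and IFNg did to the transcriptome. Nos2, the inducible nitric oxide synthase, went from 0.15 ± 0.0365 to 435 ± 21.4 RPKM (SD, n = 4). The cytokine gene Tnf went from 4.06 ± 0.619 to 1008 ± 90.9 RPKM and Il1b from 0.628 ± 0.0831 to 2020 ± 54.9 RPKM. The actin gene Actb, often used as a reference, rose too, from 886 ± 45.9 to 3786 ± 117 RPKM. Arg1, which encodes arginase and is a marker of repair-type macrophages, did not pass the test (log2 fold change -0.31, SE 0.22, limma adjusted p = 0.18) but did without 0h replicate 4 (-0.54), with the length trend removed (-0.58) and scaled to the reads in listed genes (-0.64), and the growth factor gene Vegfa fell by 1.53 (SE 0.10).

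Of 28 inflammatory mediators tested, 27 rose at 4 h and 1 fell, with a median log2 fold change of 7.07. Il1b rose by 10.28 (SE 0.22), the acute-phase gene Saa3 by 9.59, the chemokine genes Ccl5 and Cxcl10 by 9.29 and 9.18, and Il6 by 7.12. As a set they stood above the other genes (camera adjusted p = 8.6e-15, and adjusted p = 0.02 with an estimated correlation). All 30 interferon-stimulated genes rose, with a median of 3.59, among them Gbp5 and Rsad2 (both 6.58) and Cmpk2 (6.39), and the camera adjusted p of 1.6e-13 became adjusted p = 0.19 with an estimated correlation. Acod1, the gene of the enzyme that makes itaconate, rose by 8.63 (SE 0.08).

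Immediate early genes rose in 17 of 20 members and fell in 1, with a median of 2.23, led by Dusp1 (5.30), Dusp2 (4.80) and Zfp36 (4.49), feedback genes of inflammatory signalling (adjusted p = 4.3e-06, and adjusted p = 0.13 with an estimated correlation). MHC class I presentation genes rose in 15 of 16 members, with a median of 1.62 and Psmb10 (2.62), Tap1 (2.61) and Psme2 (2.46) at the front (adjusted p = 6.5e-05, and adjusted p = 0.28 with an estimated correlation). Of 21 tissue repair and growth factor genes, 16 rose and 3 fell, with a median of 1.41, Mmp13 at 7.57 and Mmp14 at 5.36 (adjusted p = 0.00085, and adjusted p = 0.13 with an estimated correlation). All 22 respiratory chain genes tested rose, by a median of 0.60, with Cycs at 2.44 (adjusted p = 0.0022, and adjusted p = 0.55 with an estimated correlation). Protein folding and heat shock genes rose in 17 of 20 members and fell in 2, with a median of 0.71, Hspa5 at 1.38 and Manf at 1.31 (adjusted p = 0.0048, and adjusted p = 0.36 with an estimated correlation). Neutrophil and granulocyte precursor markers rose in 5 of 6 members and fell in 1, with a median of 1.79 and Lcn2, which macrophages also express, at 6.99 (adjusted p = 0.04, and adjusted p = 0.36 with an estimated correlation). Among alternative activation markers 8 of 18 rose, with Il10 at 5.01, Ccl17 at 4.24 and Ccl22 at 3.78, and 7 fell. Glycolysis genes rose in 9 of 18 members and fell in 3, with Pfkfb3 at 4.27, the glucose transporter gene Slc2a1 at 2.25 and Hk2 at 1.87, and Ldha, which encodes lactate dehydrogenase A, at 0.68. The glycolysis median of 0.16 and the alternative activation median of 0.02 turned to -0.36 and -0.39 with scaling to the reads in listed genes, and Ldha (0.15) then no longer passed. The same scaling put the respiratory chain at 8 genes higher and 4 lower with a median of 0.07 (0.37 with the length trend removed), and folding and heat shock genes at 12 higher and 6 lower with a median of 0.25.

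Cholesterol synthesis genes fell at 4 h in 16 of 21 members and rose in 1, with a median of -0.84, Mvd at -2.13, Dhcr7 at -1.95 and Stard4 at -1.91 (adjusted p = 0.0024, and adjusted p = 0.52 with an estimated correlation). Of 14 LXR targets and lipid efflux genes 10 fell and 3 rose, with a median of -1.12, Scd2 at -4.95, Abcg1 at -2.38 and Scd1 at -2.34 (adjusted p = 0.025, and adjusted p = 0.28 with an estimated correlation), and with the length trend of the libraries removed this set no longer passed (adjusted p = 0.05). Cell cycle genes fell in 18 of 30 members and rose in 5, with a median of -0.52, Bub1b at -1.92 and Kif20a at -1.61 (adjusted p = 0.016, and adjusted p = 0.55 with an estimated correlation). The medians of cholesterol synthesis and cell cycle were -1.29 and -0.98 when scaled to the reads in listed genes. Among genes with a mean of at least 3 log2 units over all libraries, the named falls were those of Sesn1 (-5.12), Tmem86a (-5.04), Lyl1 (-4.91) and Ypel3 (-3.88).

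In the limma test, 4228 genes were higher and 4248 lower at 4 h than at 0 h, and 1372 and 1146 of them changed at least 2-fold. Counts adjusted over the list alone were the same for each list named in this comparison. Scaled to the reads in listed genes, the median of all genes shifted to -0.44 and the share of higher genes among those past the threshold went from 49.9% to 26.5%.

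The times after 4 h show how these early changes went on. At 8 h Nos2 had dropped to 133 ± 11.2 RPKM and Tnf to 389 ± 30.7 RPKM (SD, n = 4), which left them 6.86 and 6.27 above 0 h on the log2 scale. Arg1 had reached 63.7 ± 13.7 RPKM, 4.52 above 0 h (SE 0.22), and went on to 463 ± 45.9 RPKM at 16 h and 743 ± 181 RPKM at 24 h. Saa3 kept rising, to 11.45 above 0 h at 8 h and 12.22 at 16 h.

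At 8 h, glycolysis genes were higher than at 0 h in 16 of 18 members and lower in 2, and hypoxia (HIF) targets were higher in 15 of 21 and lower in 4, with Hilpda at 4.73 and Slc2a1 at 3.75. The lactate exporter gene Slc16a3 was up by 2.16. The heme oxygenase gene Hmox1 rose by 4.95, and the heat shock genes Hspa1b and Hspa1a by 4.32 and 4.12. Cell cycle genes were lower in 29 of 30 members and higher in 1, with Ccna2 at -3.85, Plk1 at -3.70 and Cdc20 at -3.59. The limma test put 4044 genes above and 4181 below 0 h. Sesn1 (-4.03) and Wwp1 (-3.95) were among the strongest falls. Scaled to the reads in listed genes, the median shifted to -0.41 and the share of higher genes went from 49.2% to 25.3%.

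At 16 h inflammatory mediators were still higher than at 0 h in 26 of 28 members and tissue repair genes in 18 of 21, with 1 lower. Hp, which encodes haptoglobin, was up by 7.91 and the folding factor gene Creld2 by 2.11. Ccnb2, the gene of a mitotic cyclin, was at -5.61, Stmn1 at -4.25, Gas6 at -4.03 and the mannose receptor gene Mrc1 at -2.93. In the limma test 3964 genes were higher and 3669 lower. Vegfa did not pass the test at 16 h (0.15, SE 0.10, adjusted p = 0.17) unless the groups compared were fitted alone, and it lay at -0.21 and past the threshold with scaling to the reads in listed genes, where the median of all genes was -0.31 and the share of higher genes went from 51.9% to 25.3%.

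The comparison of 24 h with 0 h sets M1 against M0 at the time of the ChIP-seq. Arg1, a repair-type gene, rose from 1.95 ± 1.23 to 743 ± 181 RPKM (SD, n = 4), a log2 fold change of 8.04 (SE 0.22, limma adjusted p = 7e-25). Vegfa rose from 11.6 ± 0.635 to 39.4 ± 9.48 RPKM (1.66, SE 0.10). Nos2 stood at 20.6 ± 3.68 RPKM, 4.21 above 0 h and well below its level at 4 h. Ldha was up by 1.14 (SE 0.09). Cell cycle and cholesterol synthesis genes were down.

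Inflammatory mediators remained higher in 24 of 28 members and lower in 1, with a median of 1.81. Saa3 was 12.30 above 0 h, Ccl5 9.47 and Ccl2 5.70, while Tnf was at 1.29, Cxcl10 at 1.57 and Il6 at 0.29, which did not pass with the length trend removed (0.15). The set gave adjusted p = 8.5e-10, and adjusted p = 0.044 with an estimated correlation. Interferon-stimulated genes were higher in 28 of 30 members and lower in 1, with a median of 0.81, Irf7 at 3.89, Isg20 at 2.42 and Oasl1 at 2.29 (adjusted p = 4.8e-07, and adjusted p = 0.26 with an estimated correlation). Tissue repair and growth factor genes rose in 19 of 21 members, with a median of 1.11, led by the metalloproteinase genes Mmp14 (4.24), Mmp13 (3.57) and Mmp9 (3.25), with adjusted p = 7.8e-07, and adjusted p = 0.033 with an estimated correlation. MHC class II genes rose in 6 of 6 members, with a median of 0.99, H2-Ab1 at 3.32 and Cd74 at 1.25 (adjusted p = 0.0035, and adjusted p = 0.26 with an estimated correlation), and MHC class I genes in 15 of 16, with a median of 0.98 and H2-T23 at 1.69 (adjusted p = 2.4e-05, and adjusted p = 0.2 with an estimated correlation). Immediate early genes were higher in 15 of 20 members and lower in 1, with a median of 0.91 (adjusted p = 0.00014, and adjusted p = 0.16 with an estimated correlation). When scaled to the reads in listed genes, 18 interferon-stimulated genes were higher and 1 lower with a median of 0.34, and the medians of MHC class II and class I were 0.53 and 0.50.

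Glycolysis genes rose at 24 h in 16 of 18 members and fell in 2, with a median of 0.68, Slc2a1 at 2.40, Pfkfb3 at 2.29 and Hk2 at 1.58 (adjusted p = 8.4e-05, and adjusted p = 0.23 with an estimated correlation). Hypoxia targets rose in 16 of 21 and fell in 3, by a mean of 1.22, with Hilpda at 3.81 (adjusted p = 0.00017, and adjusted p = 0.23 with an estimated correlation). NRF2 targets, genes of the antioxidant response, rose in 14 of 19 and fell in 3, with a median of 0.49, Hmox1 at 4.32 and the ferritin gene Fth1 at 2.63 (adjusted p = 0.0052, and adjusted p = 0.42 with an estimated correlation). Respiratory chain genes rose in 17 of 22, by a median of 0.42 (0.18 with the length trend removed) that turned to -0.05, with 7 higher and 8 lower, with scaling to the reads in listed genes (adjusted p = 0.0023, and adjusted p = 0.51 with an estimated correlation). Folding and heat shock genes rose in 18 of 20 and fell in 2, with a median of 0.75 (adjusted p = 0.00017, and adjusted p = 0.2 with an estimated correlation). In lactate transport and handling 4 of 8 genes rose, with Slc16a3 at 1.45 and its partner Bsg at 1.25, and 2 fell (adjusted p = 0.27). In the TCA cycle and pyruvate oxidation 13 of 24 genes rose and 5 fell (adjusted p = 0.27). In the amino acid and integrated stress response 12 of 23 rose and 7 fell (adjusted p = 0.28), and in the lysosome 13 of 25 rose and 6 fell (adjusted p = 0.19). With scaling to the reads in listed genes the medians of these 4 lists turned from 0.18, 0.18, 0.27 and 0.19 to -0.20, -0.28, -0.16 and -0.29. It put NRF2 targets at 8 higher and 8 lower with a median of 0.03, glycolysis at 10 higher and 2 lower with 0.21, hypoxia targets at 14 higher and 5 lower with 0.75, and folding and heat shock genes at 12 higher and 5 lower with 0.40. Histone acyl writers and erasers, enzymes that add or remove acyl groups, were listed together with Acss2 and Acly, which make acetyl-CoA. That list fell in 16 of 25 members and rose in 2, with a median of -0.20 (adjusted p = 0.062). With the same scaling 23 fell and 1 rose, with a median of -0.66.

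Cell cycle genes fell in 28 of 30 members and rose in 2, with a median of -2.85; Ccnb2 was at -5.63, Ube2c at -4.68 and Ccna2 at -4.64 (adjusted p = 3.7e-18, and adjusted p = 0.044 with an estimated correlation). All 21 cholesterol synthesis genes tested fell, with a median of -1.36, Insig1 at -1.87 and Cyp51 at -1.83 (adjusted p = 3.3e-09, and adjusted p = 0.16 with an estimated correlation). LXR targets fell in 9 of 14 members and rose in 3, with a median of -0.60 (adjusted p = 0.11), or 11 lower and 2 higher with a median of -1.04 when scaled to the reads in listed genes. Alternative activation markers were divided, 6 of 18 higher and 9 lower, or 4 and 12 with the length trend removed (adjusted p = 0.42); Arg1 rose, while Mrc1 (-1.99) and the scavenger receptor gene Stab1 (-2.28) fell. Among genes with that mean expression, Stmn1 (-4.35), Fcrls (-3.67), Cbr2 (-2.93), Fads2 (-2.91) and Gas6 (-2.86) fell most, and Hp rose by 6.57.

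Markers of other cells gave few genes to test. Macrophage identity genes went both ways, 10 of 20 higher and 7 lower, with a median of 0.21 that turned to -0.22 with scaling to the reads in listed genes (adjusted p = 0.28). Of 15 neutrophil and granulocyte precursor markers 6 were tested, of which 3 were higher, with Lcn2 at 8.49, and 1 lower (adjusted p = 0.11). Of 12 dendritic cell markers 4 were tested, 2 higher and 1 lower (adjusted p = 0.28), and of 14 stromal and endothelial markers 4 were tested, 2 higher and 1 lower (adjusted p = 0.42). Of 18 lymphocyte markers 2 were tested and 1 fell, and none of the 14 erythroid and mast cell markers was listed. Mitochondrially encoded transcripts, a sign of RNA quality, were lower in 6 of 12 members and higher in 1, with a median of -0.36 (adjusted p = 0.3). With the length trend removed 11 were lower, with a median of -0.93, and the set passed (adjusted p = 0.032, and adjusted p = 0.55 with an estimated correlation), and scaled to the reads in listed genes 10 were lower, with a median of -0.82. In the limma test 3966 genes were higher and 3713 lower at 24 h, and 623 and 534 of them changed at least 2-fold. Counts adjusted over the list alone were the same for every list at 24 h. Actb did not pass the test (0.17, SE 0.08, adjusted p = 0.06), passed without 0h replicate 1 (0.20), 24h replicate 1 (0.20) or 24h replicate 2 (0.19) and with edgeR (0.17), DESeq2 (0.19) and median-of-ratios scaling (0.19), and turned to -0.32, past the threshold, with scaling to the reads in listed genes. That scaling put the median of all genes at -0.38, with 1680 genes higher and 6701 lower.

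**Figure D2:**
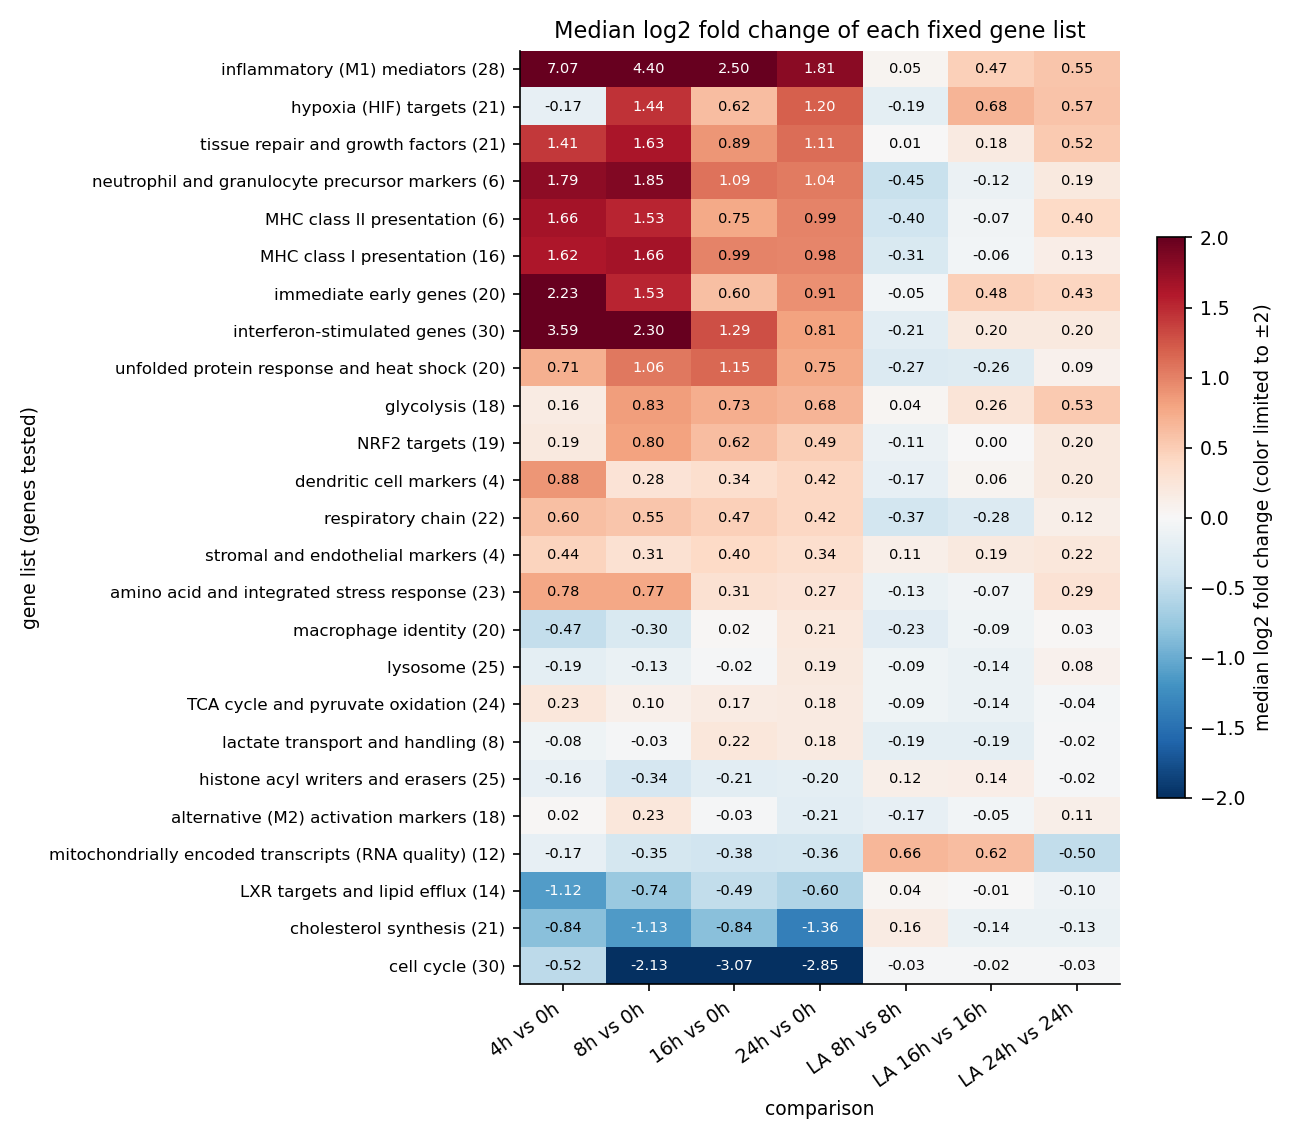
Median log2 fold change (color and printed value) of the gene lists fixed in advance that had at least 4 genes tested (vertical axis, with the number of genes tested) in 7 comparisons (horizontal axis). Inflammatory mediators went from 7.07 at 4 h to 1.81 at 24 h and cell cycle genes from -0.52 to -2.85.

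Compared directly, 24 h differed from 4 h in both directions. Inflammatory mediators were lower at 24 h than at 4 h in 24 of 28 members and higher in 2, with a median of -4.13; Cxcl10 was at -7.61, Il6 at -6.83, Ccl4 at -6.77 and Tnf at -6.36. Interferon-stimulated genes were lower in 28 of 30 and higher in 2, with Cmpk2 at -6.25 and Rsad2 at -5.97. Arg1 was up by 8.35 (SE 0.22), Gdf15 by 4.36 and Vegfa by 3.19. Hypoxia targets were higher in 15 of 21 and lower in 1, with Ankrd37 at 2.78, and lysosomal genes in 17 of 25 and lower in 4, with the cathepsin genes Ctsl at 1.74 and Ctsd at 1.32. Glycolysis genes were higher in 13 of 18 and lower in 4. Tissue repair and growth factor genes were higher in 5 of 21 and lower in 12, with a median of -0.43, and alternative activation markers higher in 3 of 18 and lower in 12, with a median of -0.88. Tmem86a (4.85), Clec4n (4.56) and Scd2 (4.23) were higher, and Hcar2 (-6.67) and Ptgs2 (-6.65) lower. The limma test put 4203 genes higher and 4108 lower at 24 h than at 4 h.

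The lactic acid arm asks how added lactic acid altered the same course. At 8 h, 4 h after the addition, Nos2 was higher with lactic acid, 268 ± 22.3 against 133 ± 11.2 RPKM (SD, n = 4), a log2 fold change of 1.01 (SE 0.13, limma adjusted p = 6.8e-08). Arg1 was lower, 24.1 ± 5.52 against 63.7 ± 13.7 RPKM (-1.37, SE 0.22), and Ldha was lower by 0.39 (SE 0.09). Changes were small: 3196 genes were higher and 3581 lower, but only 44 and 12 of them changed at least 2-fold.

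Expression at this time separated by gene length. Across genes, the log2 fold change at LA 8h against 8h rose with gene length (Spearman rho 0.53, with genes not independent replicates), and Lamc1 (1.19), Dync1h1 (1.16), Chd4 (1.15) and Lrp1 (1.13) were among those that rose most while Scand1 (-1.57), BC147527 (-1.26), H1f0 (-1.09) and Yeats4 (-1.05) were among those that fell most. The slope of expression on length lay between 0.130 and 0.163 per doubling in the LA 8h libraries and between -0.081 and -0.004 in the 8h libraries. The same rho was 0.37 at 16 h and -0.16 at 24 h. In the other comparisons it was -0.09 at 4 h, -0.17 at 8 h, -0.25 at 16 h and -0.30 at 24 h against 0 h, and -0.11 for 24 h against 4 h.

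**Figure D3:**
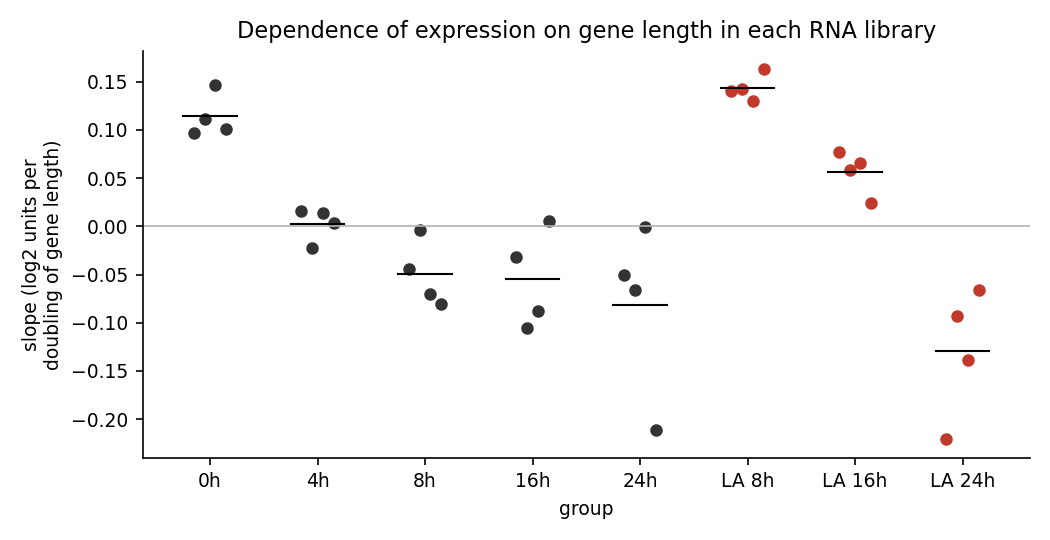
Slope of each RNA library's log2 expression, relative to the gene's mean, on log2 gene length (vertical axis, log2 units per doubling) by group (horizontal axis); points are libraries, black without and red with lactic acid, and lines are group means. The 4 LA 8h libraries lie at 0.130 to 0.163 and the 4 libraries of 8h at -0.081 to -0.004.

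Respiratory chain genes encoded in the nucleus were lower at LA 8h in 19 of 22 members, by a median of -0.37, with Cox5b at -0.69, Ndufb8 at -0.57 and Cox5a at -0.52 (adjusted p = 0.0016, and adjusted p = 0.9 with an estimated correlation). With the length trend removed the median was -0.19, 13 were lower and 1 higher, and the adjusted p was 0.048 (and adjusted p = 0.99 with an estimated correlation); Cox5a then no longer passed (-0.09). Mitochondrially encoded transcripts were higher in 8 of 12 members, by a median of 0.66, with ND5 at 1.01, COX1 at 0.98 and ND4 at 0.96 (adjusted p = 0.033, and adjusted p = 0.9 with an estimated correlation), and by a median of 1.09 with the length trend removed. Inflammatory mediators were higher in 11 of 28 members and lower in 7 (adjusted p = 0.46); the prostaglandin synthase gene Ptgs2 was at 1.58 and Ccl3 at 0.78. With the length trend removed 16 of them were higher and 4 lower, with a median of 0.33 and adjusted p = 0.0083 (and adjusted p = 0.99 with an estimated correlation). Hspa1a was up by 1.17 and Hspa1b by 0.80, and the acetyltransferase genes Kat6a and Ep300 by 0.76 and 0.75. Tnf (0.21, adjusted p = 0.022) and Cxcl10 (0.38, adjusted p = 0.014) lay just past the threshold, and leaving out 1 library put Tnf at 0.15 without 8h replicate 2 and at 0.19 without LA 8h replicate 1 or 2, none past it. Cxcl10 lay at 0.24 without 8h replicate 2 and at 0.32 without LA 8h replicate 2 or 4, again not past it. Of the 6 neutrophil and granulocyte precursor markers tested 5 were lower at LA 8h, with a median of -0.45 (adjusted p = 0.29). Il1b, Vegfa and Actb did not pass (-0.01, 0.13 and 0.02), and Vegfa (0.21) did with scaling to the reads in listed genes.

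At 16 h lactic acid kept Nos2 high. It stood at 107 ± 15.9 RPKM against 8.51 ± 1.74 without (SD, n = 4), a log2 fold change of 3.50 (SE 0.13, limma adjusted p = 3.6e-19). Ptgs2 was higher by 2.18 and Il1b by 1.62 (SE 0.22). Vegfa was higher by 0.91 (SE 0.10). Arg1 (0.20, SE 0.22, adjusted p = 0.44), Tnf (0.02), Ldha (0.02) and Actb (0.13) did not pass the test, and Actb (0.19) did with the length trend removed.

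Inflammatory mediators were higher at LA 16h in 16 of 28 members and lower in 4, with a median of 0.47 (adjusted p = 0.0008, and adjusted p = 0.54 with an estimated correlation). Interferon-stimulated genes were higher in 14 of 30 and lower in 2, with a median of 0.20, Oasl1 at 0.81 and Rsad2 at 0.75 (adjusted p = 0.023, and adjusted p = 0.81 with an estimated correlation). Hypoxia targets were higher in 14 of 21 and lower in 1, with a median of 0.68 and Slc2a1 at 1.05 (adjusted p = 1.3e-05, and adjusted p = 0.46 with an estimated correlation). Glycolysis genes were higher in 11 of 18 and lower in 1, with a median of 0.26, Pfkfb3 at 0.99 and Hk1 at 0.98 (adjusted p = 0.00055, and adjusted p = 0.54 with an estimated correlation). Immediate early genes were higher in 15 of 20, with a median of 0.48, Ier3 at 1.10, Fosl2 at 0.98 and Dusp1 at 0.84 (adjusted p = 1.4e-05, and adjusted p = 0.37 with an estimated correlation). Tissue repair genes were higher in 10 of 21, or 11 adjusted over the list alone, and lower in 3, with a median of 0.18 (0.29 with the length trend removed) and Thbs1 at 1.28 (adjusted p = 0.049, and adjusted p = 0.54 with an estimated correlation). Hspa1b was up by 1.56 and Hspb1 by 1.35. Respiratory chain genes were lower in 15 of 22, with Ndufb8 at -0.62 (adjusted p = 0.0027, and adjusted p = 0.81 with an estimated correlation), by a median of -0.28, or -0.17 with the length trend removed. Mitochondrially encoded transcripts were higher in 8 of 12, with a median of 0.62, COX2 at 0.82 and COX1 at 0.67 (adjusted p = 0.011, and adjusted p = 0.81 with an estimated correlation). The calprotectin genes S100a8 (-0.89) and S100a9 (-0.83) and the replication gene Mcm5 (-0.81) were lower. Nxpe5 (-1.37), Lsm7 (-1.08), Ccl12 (-1.08), Timm10 (-1.07) and Nme4 (-0.98) were the lower genes named by rule. The limma test put 2999 genes higher and 3081 lower, and 20 and 6 of them changed at least 2-fold.

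At 24 h Nos2, Arg1 and Vegfa were all higher with lactic acid. Nos2 was at 194 ± 38.4 RPKM with and 20.6 ± 3.68 without it (SD, n = 4), a log2 fold change of 3.17 (SE 0.13, limma adjusted p = 3.2e-18). Arg1 was at 1955 ± 538 against 743 ± 181 RPKM (1.39, SE 0.22, adjusted p = 6.2e-06). Vegfa was at 75.8 ± 2.21 against 39.4 ± 9.48 RPKM (0.96, SE 0.10). Il1b was higher by 1.93 (SE 0.22), Tnf by 0.57 (SE 0.08) and Ldha by 0.66 (SE 0.09), and Actb was at -0.33, which did not pass when the groups of this comparison were fitted alone.

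Inflammatory mediators were higher at LA 24h in 21 of 28 members and lower in 1, with a median of 0.55, led by Nos2, Ptgs2 (2.02), Il1b and Cxcl2 (1.91), with adjusted p = 2.8e-09, and adjusted p = 0.072 with an estimated correlation. Tissue repair and growth factor genes were higher in 16 of 21 and lower in 2, with a median of 0.52, Gdf15 at 1.82 and Spp1 at 1.38 (adjusted p = 1e-06, and adjusted p = 0.034 with an estimated correlation). Hypoxia targets were higher in 17 of 21 and lower in 2, with a median of 0.57, Hilpda at 1.78 and Ankrd37 at 1.34 (adjusted p = 2.2e-09, and adjusted p = 0.072 with an estimated correlation). Glycolysis genes were higher in 15 of 18 and lower in 1, with a median of 0.53, Slc2a1 at 1.07, Pfkfb3 at 0.82 and Pfkp at 0.78 (adjusted p = 3e-08, and adjusted p = 0.11 with an estimated correlation). Immediate early genes were higher in 14 of 20 and lower in 2, with a median of 0.43, Dusp1 at 1.77 and Ier3 at 0.97 (adjusted p = 2.8e-05, and adjusted p = 0.11 with an estimated correlation). In the amino acid and integrated stress response 13 of 23 genes, or 14 adjusted over the list alone, were higher and 5, or 6 adjusted over the list alone, lower, with a median of 0.29, Ddit4 at 1.41, Atf3 at 1.34 and Ddit3 at 1.15 (adjusted p = 0.025, and adjusted p = 0.61 with an estimated correlation). NRF2 targets were higher in 9 of 19 and lower in 1, with the cystine transporter gene Slc7a11 at 0.85 and Nqo1 at 0.64 (adjusted p = 0.027, and adjusted p = 0.61 with an estimated correlation), and their median of 0.20 turned to -0.01 with scaling to the reads in listed genes. That scaling put the medians of tissue repair and glycolysis at 0.33 and 0.32, and the integrated stress response at 7 higher and 6 lower with a median of 0.11.

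MHC class II genes were higher at LA 24h in 6 of 6 members, with a median of 0.40, H2-Ab1 at 0.88 and Cd74 at 0.43 (adjusted p = 0.017, and adjusted p = 0.61 with an estimated correlation). Cd74 was no longer past the threshold without 24h replicate 2 (0.29) or without LA 24h replicate 1 (0.35), nor with the groups of this comparison fitted alone, and neither was Cxcl10 (0.45) without 24h replicate 2 (0.30). With scaling to the reads in listed genes Cd74 (0.22) and Cxcl10 (0.24) did not pass either, and 2 of the 6 MHC class II genes were higher, with a median of 0.20. Alternative activation markers went both ways, with Tgm2 at 0.93 and Mrc1 at -1.06, 7 of 18 higher and 3 lower, and their median of 0.11 turned to -0.01 with that scaling. The monocarboxylate transporter gene Slc16a3 (0.70) and its partner Bsg (0.63) rose, but the median of the 8 lactate transport and handling genes was -0.02. With that scaling 3 of the 8 were higher and 4 lower, with a median of -0.18. Cholesterol synthesis genes were lower in 8 of 21 and higher in 1, with a median of -0.13, or -0.30 with that scaling (adjusted p = 0.011, and adjusted p = 0.61 with an estimated correlation). Mitochondrially encoded transcripts, higher with lactic acid at 8 h and 16 h, were lower at 24 h in 9 of 12, by a median of -0.50, with ATP8 at -1.26, ND3 at -0.90 and ND6 at -0.78 (adjusted p = 0.0022, and adjusted p = 0.61 with an estimated correlation). All 4 stromal and endothelial markers tested were higher, with a median of 0.22 (adjusted p = 0.095), as were 2 of 4 dendritic cell markers (adjusted p = 0.25) and 2 of 6 neutrophil and granulocyte precursor markers (adjusted p = 0.35). With the scaling to reads in listed genes 1 stromal and endothelial marker was higher. Mcm5 (-0.89), Nxpe5 (-1.27), Mat2a (-1.05) and Srsf1 (-0.99) fell too. The limma test put 2532 genes higher and 2153 lower, and 69 and 4 of them changed at least 2-fold. Fitted with the groups of this comparison alone the counts were 1200 and 815. Libraries within 24h and LA 24h differed more than those within 8h and LA 8h. The SE and adjusted p of the main fit, which pools the spread, may therefore be too small here. Scaled to the reads in listed genes the median of all genes was -0.15 and the share of higher genes 18.1%, against 54.0%.

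Whether lactic acid acted differently at 24 h than at 8 h was tested as an interaction. The effect on Arg1 was larger at 24 h by 2.76 (SE 0.31, limma adjusted p = 2.3e-08), turning from lower to higher. It was larger by 2.16 for Nos2 (SE 0.18), 1.94 for Il1b (SE 0.31), 1.05 for Ldha, 0.82 for Vegfa and 0.37 for Tnf, and smaller for Actb (-0.35). For Tnf the sign turned to -0.01 with the length trend removed, which did not pass, and the value was 0.08 with scaling to the reads in listed genes. For Cxcl10 the difference did not pass (0.07). Il6 lay below 1 RPKM at 24 h and its difference was 0.03 on this scale, but 0.77 and past the threshold with a pseudocount of 0.1, and 1.06 and past it with edgeR or DESeq2 on the recovered reads.

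By list, the interaction was positive for hypoxia targets in 17 of 21 members and negative in 2, with a median of 0.96 and Hilpda at 2.55 (adjusted p = 1e-05, and adjusted p = 0.44 with an estimated correlation). It was positive for glycolysis in 12 of 18, or 13 adjusted over the list alone, and negative in 1, with a median of 0.57 and Pgam1 and Pgk1 both at 1.03 (adjusted p = 0.00084, and adjusted p = 0.49 with an estimated correlation). For tissue repair genes it was positive in 13 of 21 and negative in 1, with a median of 0.62 (adjusted p = 0.0014, and adjusted p = 0.44 with an estimated correlation). For immediate early genes it was positive in 12 of 20 and negative in 3, with a median of 0.43, Dusp1 at 2.11 and Atf3 at 1.93 (adjusted p = 0.0025, and adjusted p = 0.49 with an estimated correlation). For MHC class II genes it was positive in 6 of 6, with a median of 0.75 and H2-Ab1 at 1.52 (adjusted p = 0.013, and adjusted p = 0.49 with an estimated correlation; adjusted p = 0.11 with the length trend removed). Inflammatory mediators were positive in 18 of 28 and negative in 2, with a median of 0.49 and Cxcl2 at 1.43 (adjusted p = 0.00084, and adjusted p = 0.49 with an estimated correlation), and that set did not pass with the length trend removed (adjusted p = 0.13). Respiratory chain genes were positive in 17 of 22, or 18 adjusted over the list alone, with a median of 0.52, Cox4i1 at 0.93 and Ndufb8 at 0.81 (adjusted p = 0.00034, and adjusted p = 0.53 with an estimated correlation). Interferon-stimulated genes were positive in 14 of 30, with a median of 0.27 (adjusted p = 0.013, and adjusted p = 0.53 with an estimated correlation). NRF2 targets were positive in 11 of 19 and negative in 1, with a median of 0.27 that turned to -0.03 with scaling to the reads in listed genes (adjusted p = 0.017, and adjusted p = 0.53 with an estimated correlation). Cholesterol synthesis genes were negative in 10 of 21 and positive in 1, with a median of -0.27 (adjusted p = 0.013, and adjusted p = 0.53 with an estimated correlation). Mitochondrially encoded transcripts were negative in 11 of 12, with a median of -1.07, ATP8 at -1.84, ND6 at -1.48, ND5 at -1.45 and ND2 at -1.42 (adjusted p = 0.00022, and adjusted p = 0.49 with an estimated correlation), and Mrc1 was at -1.33. With the libraries scaled to the reads in listed genes, 8 interferon-stimulated genes were positive and 5 negative with a median of 0.03, and 13 respiratory chain genes positive and 3 negative with 0.22. The medians were 0.27 for inflammatory mediators, 0.33 for tissue repair, 0.27 for glycolysis, 0.47 for MHC class II, 0.24 for immediate early genes and -0.53 for cholesterol synthesis. With the length trend removed they were 0.23 for the respiratory chain, 0.30 for inflammatory mediators, 0.39 for MHC class II, 0.19 for immediate early genes and -1.62 for mitochondrially encoded transcripts. The limma test gave 3253 genes with a larger and 2956 with a smaller effect at 24 h. Scaled to the reads in listed genes the median was -0.20 and the share of positive genes 25.7%, against 52.4%. The length trend ran in the negative direction here, with a Spearman rho of -0.52 across genes.

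Across genes, which are not independent replicates, the effect of lactic acid at 24 h correlated with the change from 0 h to 16 h (Pearson r 0.29, Spearman rho 0.28, 9942 genes, no library shared), and the effects of lactic acid at 8 h and at 24 h did not follow each other (r -0.01, rho -0.04). With the length trend removed, the second r was 0.09.

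The spike-in reads set all mouse reads of a library, background included, against the foreign chromatin in the same library. Spike-in reads made up 1.405% of the M0 H3K18la library (21765076 mouse reads) and 0.670% of the M1 H3K18la library (21006731). In H3K18ac they made up 0.143% in M0 (36576826) and 0.153% in M1 (32948615). Exact 95% binomial intervals on these shares, which cover counting error only, ran from 1.400 to 1.410%, 0.666 to 0.673%, 0.142 to 0.145% and 0.152 to 0.154%. The deposited table multiplies the M1 mouse reads by the ratio of spike-in reads M1 over M0, 0.46 for H3K18la and 0.96 for H3K18ac, which gives 9663096 and 31630670 scaled mouse reads, 0.444 and 0.865 of M0. Multiplying by the inverse ratio (2.188 and 1.040), which holds the spike-in equal, gives 2.112 and 0.937 of M0. If both states received equal spike-in chromatin, only the inverse ratio puts them on the same scale. The H3K18la library of M1 then held more mouse DNA than that of M0. The share of background in it was not measured, so this is not a level of the mark alone. The read counts do not show whether the spike-in was equal, and with 1 library per state the difference has no replicate check.

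Peak lists show where the marks lay, per the genome build mm10. H3K18la had 21885 peaks in M0, covering 34.8 Mb, and 16139 in M1, covering 25.8 Mb. H3K18ac had 41493 peaks in M0 (112.1 Mb) and 42237 in M1 (136.3 Mb). Of the H3K18la peaks 53.2% in M0 and 56.2% in M1 lay within 2 kb of either end of a gene, against 38.0% and 37.0% of the H3K18ac peaks. Median fold enrichment was 5.41 in M0 and 4.16 in M1 for H3K18la, and 3.93 and 3.56 for H3K18ac.

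H3K18la sat nearly everywhere on H3K18ac. An H3K18ac peak overlapped 98.9% of the H3K18la peaks in M0 and 94.7% in M1, and an H3K18la peak overlapped 45.8% of the H3K18ac peaks in M0 and 29.9% in M1. The H3K18ac lists are longer, and with equal numbers of peaks the last 2 shares were 80.3% and 69.7%, while with at least 50% of the peak covered they were 25.9% and 11.3%. Between states, 57.2% of the M0 H3K18la peaks were overlapped in M1 (exact 95% interval 56.6 to 57.9%) and 77.6% of the M1 peaks in M0, or 69.5% and 70.1% with equal numbers of peaks. Of M0 peaks split into 4 by fold enrichment, 1261 of the 5471 weakest and 5030 of the 5472 strongest were overlapped in M1. For H3K18ac, 76.2% of all M0 peaks were overlapped in M1 and 70.4% of all M1 peaks in M0. Circular shifts of the peaks along the chromosomes gave a mean of 2.1% to 9.1% for these 8 shares, so each was above what position-blind placement gives.

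Nos2 and Cxcl10 had an H3K18la peak near a gene end in M1 and in M0 none. The Nos2 peak, on chromosome 11 from 78912071 to 78924307, had a fold enrichment of 10.26, higher than 97.8% of the peaks in its list, and the Cxcl10 peak, on chromosome 5 from 92347010 to 92354389, had 6.69. Both genes had an H3K18ac peak near a gene end in each state, with a higher fold enrichment in M1. It was 3.95 in M0 and 8.58 in M1 at Nos2, and 3.88 and 6.53 at Cxcl10. Il1b and Il6 had an H3K18ac peak in both states and no H3K18la peak in either. Tnf, Arg1, Vegfa, Ldha and Actb had an H3K18la peak in both. At Arg1 its fold enrichment was 4.74 in M0 and 3.58 in M1, at Vegfa 5.81 and 3.31, at Tnf 9.10 and 8.38, and at Actb 22.49 and 14.05. Each was lower in M1, as was the median over all shared H3K18la sites, 4.49 against 6.78. These values come from different libraries and do not by themselves show a loss of the mark at these genes. Gene positions were those of Nos2 (ENSMUSG00000020826), Cxcl10 (ENSMUSG00000034855), Il1b (ENSMUSG00000027398), Il6 (ENSMUSG00000025746), Tnf (ENSMUSG00000024401), Arg1 (ENSMUSG00000019987), Vegfa (ENSMUSG00000023951), Ldha (ENSMUSG00000063229) and Actb (ENSMUSG00000029580).

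The strongest H3K18la peaks without a counterpart in the other state were named by rule. In M1 they lay over Acod1 and the transcript Gm41235 on chromosome 14 from 103045336 to 103050344 (fold enrichment 18.27), over Slfn1 and Gm51911 on chromosome 11 from 83115825 to 83121053 (15.78), and 65 bp from Tgtp2 on chromosome 11 from 49064277 to 49064851 (11.96). Acod1 rose by 8.63 at 4 h in the RNA, and Slfn1 and Tgtp2 belong to interferon-induced gene families. In M0 they lay over Tpx2, a mitotic spindle gene, on chromosome 2 from 152847873 to 152848849 (15.60), over Rangap1 on chromosome 15 from 81729189 to 81729977 (15.02), and 8647 bp from 1700027F06Rik on chromosome 6 from 124373133 to 124377510 (14.42). For H3K18ac the M1 peaks lay over Crkl on chromosome 16 from 17465483 to 17471081 (8.78), over Gm12185 on chromosome 11 from 48925636 to 48929036 (8.07) and 13140 bp from Gm41829 on chromosome 19 from 29221577 to 29224917 (9.42). The M0 peaks lay 4591 bp from Secisbp2l on chromosome 2 from 125731762 to 125732395 (7.64), over Fam98c on chromosome 7 from 29155310 to 29156789 (7.34) and over 4930521O17Rik on chromosome 10 from 67964897 to 67967406 (6.88).

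The series asks how the marks relate to expression. Of 9825 tested genes with a position, 7313 had an H3K18la peak within 2 kb of a gene end in both states, 141 in M1 and in M0 none, 1571 in M0 and in M1 none, and 800 in neither. For H3K18ac the numbers were 8806, 172, 331 and 516. With peaks of a -log10 q of at least 5 alone, the genes with a peak in M1 alone and in M0 alone were 110 and 3141 for H3K18la and 367 and 986 for H3K18ac. At shared sites the median fold enrichment of H3K18la was 4.49 in M1 and 6.78 in M0. A gene with the peak in M0 alone may therefore hold the mark in M1 below the threshold. The class does not by itself show a loss of the mark. Genes with an H3K18la peak were expressed at a higher level in the same state, with a median of 6.86 RPKM against 2.47 without in M0 and 7.61 against 3.03 in M1. The same held for H3K18ac, with 6.71 against 2.52 in M0 and 6.76 against 2.08 in M1.

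Genes that had an H3K18la peak in M1 alone were induced from the first time point on. Of the 141, 108 were higher and 19 lower at 4 h, with a mean log2 fold change of 1.83, and 97 were higher and 22 lower at 24 h, with a mean of 1.01 (camera adjusted p = 4e-12 and adjusted p = 5.1e-09, which with an estimated correlation were adjusted p = 0.0014 and adjusted p = 0.002). The 141 include Nos2, Cxcl10, Ccl5, H2-Ab1 and Mmp14. Of all 9825 tested genes with a position, 42.6% were higher and 42.7% lower at 4 h, and 39.8% and 37.4% at 24 h. The 1571 genes with the peak in M0 alone had a mean of -0.21 at 4 h and -0.26 at 24 h, with 435 higher and 779 lower at 24 h (adjusted p = 4.6e-05, and adjusted p = 0.002 with an estimated correlation). H3K18ac behaved alike in direction, with means of 1.13 at 4 h and 0.50 at 24 h for its 172 M1-only genes (adjusted p = 2.3e-06 and adjusted p = 0.0013) and -0.22 and -0.51 for its 331 M0-only genes (adjusted p = 0.0059 and adjusted p = 5.1e-09). At 4 h the latter gave adjusted p = 0.1 with an estimated correlation. Without the genes that also had an M1-only H3K18ac peak, the remaining 96 M1-only H3K18la genes had a mean of 1.43 at 4 h and 0.99 at 24 h (adjusted p = 2.3e-06 and adjusted p = 9.3e-07). At 8 h the median was 0.83 for these 96, 1.17 for the 141 and 0.43 for the 172, and at 24 h it was 0.52, 0.51 and 0.21. With peaks of a -log10 q of at least 5 alone, 53 genes took the place of the 96. The 96 include Nos2 and Cxcl10, whose H3K18ac peak was present in both states but had a higher fold enrichment in M1. This class therefore does not hold H3K18ac unchanged.

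Lactic acid moved the M1-only H3K18la genes little. Their median was -0.08 at LA 8h (adjusted p = 0.75), 0.10 at LA 16h (adjusted p = 0.017, adjusted p = 0.27 with an estimated correlation, and adjusted p = 0.18 with peaks of a -log10 q of at least 5) and 0.14 at LA 24h, where 55 of the 141 were higher and 15 lower (adjusted p = 0.0065, and adjusted p = 0.099 with an estimated correlation). Among all 9825 tested genes with a position, 25.6% were higher and 21.5% lower at LA 24h, against 39.0% and 10.6% of the 141. The M0-only genes had a median of -0.05 at LA 24h (adjusted p = 0.011, and adjusted p = 0.091 with an estimated correlation). With the length trend removed the LA 24h medians were 0.08 for the M1-only and -0.08 for the M0-only genes. With peaks of a -log10 q of at least 5 the M1-only median at LA 16h was 0.03.

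**Figure D4:**
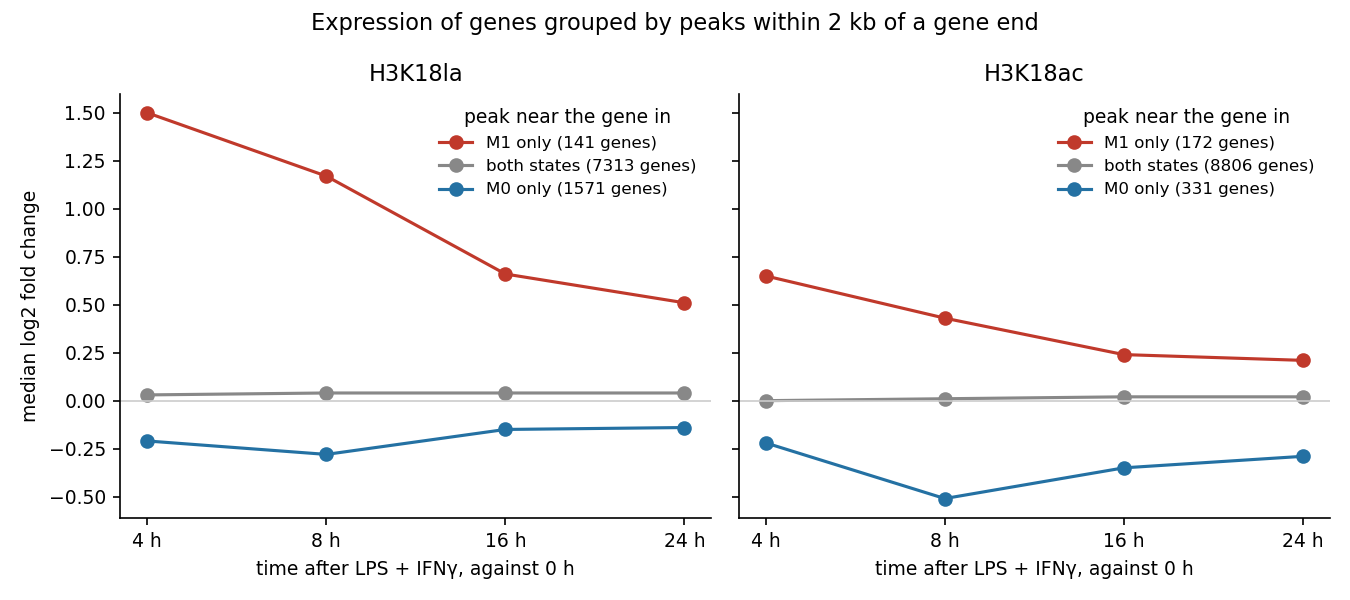
Median log2 fold change against 0 h (vertical axis) at each time (horizontal axis) of genes grouped by where they had an H3K18la (left) or H3K18ac (right) peak within 2 kb of a gene end. The 141 genes with an H3K18la peak in M1 alone went from 1.17 at 8 h to 0.51 at 24 h.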

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

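The tests of explanations and of other splits in this part were all chosen only after the result was seen.

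Of 112 groups of 4 libraries tested for a library far from the others, 4 held one, and chance gives about 1 in 20. Nos2 in 16h replicate 4 was at 11.11 RPKM (others 7.398 to 7.854), and Tnf in LA 16h replicate 2 at 43.82 RPKM (34.61 to 36.04). Il1b was at 0.7522 RPKM in 0h replicate 2 (0.5808 to 0.5987) and at 2102 RPKM in 4h replicate 1 (1986 to 1998). The libraries of 24h and LA 24h that stood apart on the second principal component were not among them (gap over range 0.685 and 0.567).

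The effect of lactic acid differed between 24 h and 8 h by a test of the difference itself, with 3253 genes larger and 2956 smaller at 24 h. By gene the difference was 2.16 for Nos2, 0.37 for Tnf, 1.94 for Il1b, 2.76 for Arg1, 0.82 for Vegfa, 1.05 for Ldha and -0.35 for Actb.

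Other splits of the same libraries were compared with the real split for the number of genes called. For 4 h against 0 h, 1 of 35 splits, the real one, called as many (8476, highest other 5546). The same held, 1 of 35, for 8 h (8225 against 5152), 16 h (7633 against 4654), 24 h (7679 against 4802) and 24 h against 4 h (8311 against 5399). It held for lactic acid at 8 h (6777 against 1), 16 h (6080 against 4228) and 24 h (4685 against 4372), and for the difference between 24 h and 8 h in 1 of 100 (6209 against 5920). The real split called the most genes each time. Nearly all listed genes had passed the authors' test on these same libraries, which favors the real split. The gene counts therefore cannot by themselves exclude chance. As many lists were called in 10 of 35 splits at 4 h (11, highest other 12) and 13 of 35 at 24 h (13, 16). For lactic acid it was 27 of 35 at 8 h (2, 9), 7 of 35 at 16 h (8, 8), 8 of 35 at 24 h (10, 12) and 20 of 100 for the difference (11, 15). Splits that exchange 1 library per group keep part of the real difference, and camera sets genes against each other. The list counts therefore cannot decide about chance.

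Respiratory chain genes were lower with lactic acid at 8 h, where expression also followed gene length. The mean of the list per library differed by -0.42 (SE 0.04), and by -0.21 (SE 0.03) with the length trend removed, so the trend is not the whole cause. The mean slopes of the LA 8h and 8h libraries differ by 0.194 (SE 0.034 with the spread pooled over all 8 groups, and 0.064 with that of 24h, the group that varies most), which argues against a slope that varies by chance. A difference in preparation between the groups, which the labels do not give, and an effect of lactic acid on long transcripts both stay open.

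Inflammatory mediators were higher with lactic acid at 24 h, by 0.71 (SE 0.07) in the mean of the list per library. Without both libraries that stood apart the difference was 0.73 (SE 0.04), with the length trend removed it was 0.65 (SE 0.04), and scaled to the reads in listed genes the median of the list was 0.37, with that of all genes at -0.15. These values argue against the libraries that stood apart, the length trend and the scaling as the whole cause. Mitochondrially encoded transcripts, a sign of RNA quality, were lower at LA 24h (median -0.50) and all 4 stromal and endothelial markers tested higher (median 0.22). RNA quality, other cells, batches that the labels do not give and an effect of lactic acid stay open.

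H3K18la had fewer peaks in M1 than in M0, a ratio of 0.737. The ratio of mouse reads was 0.965, which argues against depth as the whole cause. At shared sites the median fold enrichment was 4.49 in M1 and 6.78 in M0, a ratio of 0.662, against 0.915 for H3K18ac. A lower enrichment of the M1 library fits this ratio. The spike-in puts M1 at 0.444 of M0 as deposited and at 2.112 with the inverse factor. Only the inverse factor holds the spike-in equal, so the M1 library held more mouse DNA if both states received equal spike-in chromatin. That ratio counts all mouse reads, background included, so it is not a level of the mark alone. The read counts do not show whether the spike-in was equal, and with 1 library per state the ratio has no replicate check.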

How the results depend on the processing

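Scaling to the reads in listed genes, the length trend removed, both libraries left out and all fits on recovered reads were chosen after seeing the data. Counts of genes stayed within 1.5 times under median-of-ratios scaling of the RPKM, no filter, a pseudocount of 0.1, the length trend removed, edgeR with either factors, DESeq2, and without both libraries that stood apart. Depth may limit genes near 1 RPKM and weak peaks, which was not tested, and the ChIP-seq has no replicates.

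With each library left out in turn, counts higher and lower ranged from 4085 to 4187 and 4016 to 4200 at 4 h, 3942 to 4017 and 3949 to 4142 at 8 h, 3850 to 3956 and 3375 to 3671 at 16 h, 3826 to 3958 and 3433 to 3719 at 24 h, and 4122 to 4192 and 3961 to 4145 for 24 h against 4 h. For lactic acid they ranged from 3005 to 3145 and 3304 to 3531 at 8 h, 2675 to 3088 and 2617 to 3157 at 16 h, 2226 to 2969 and 1907 to 2467 at 24 h, and 3012 to 3568 and 2750 to 3217 for the difference.

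The samples share only a number: same-number correlations ran from -0.643 to 0.511, and 9 of 32 libraries correlate best with their own number. A replicate block gave 4222 for 4h vs 0h: genes higher, 4242 for 4h vs 0h: genes lower, 2520 for LA 24h vs 24h: genes higher and 2142 for LA 24h vs 24h: genes lower, and changed no call of a list, named gene or peak class.

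With a change of at least 2-fold, a stricter threshold by construction, counts higher and lower were 1372 and 1146 at 4 h, 1119 and 1019 at 8 h, 653 and 623 at 16 h, 623 and 534 at 24 h, 1100 and 1328 for 24 h against 4 h, 44 and 12 at LA 8h, 20 and 6 at LA 16h, 69 and 4 at LA 24h, and 236 and 70 for the difference. With only the groups compared, LA 24h gave 1200 and 815, while LA 8h gave 3328 and 3736 and LA 16h gave 2975 and 3124. Each of these fits held fewer samples than the main fit, so fewer samples alone do not account for the fall at LA 24h. The main fit pools the spread over all groups, and the cause was not tested. Scaled to the reads in listed genes, counts were 2329 and 6448 at 4 h, 2196 and 6473 at 8 h, 2081 and 6160 at 16 h, 1680 and 6701 at 24 h, 1038 and 4683 at LA 24h, and 1670 and 4829 for the difference, since that scaling shifts all genes.

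The main list calls rest on a preset correlation between genes of 0.01. At 4 h the estimated correlation of the lists that lost their call ran from 0.07 for LXR targets to 0.70 for respiratory chain. With an estimated correlation 50 of 55 list calls were lost. The adjusted p were, at 4 h, 0.19 for interferon-stimulated genes, 0.13 for tissue repair, 0.55 for respiratory chain and cell cycle, 0.52 for cholesterol synthesis, 0.28 for LXR targets and MHC class I, 0.36 for heat shock and neutrophil markers and 0.13 for immediate early genes. At 24 h they were 0.26 for interferon-stimulated genes and MHC class II, 0.23 for glycolysis and hypoxia, 0.51 for respiratory chain, 0.16 for cholesterol synthesis and immediate early genes, 0.2 for MHC class I and heat shock and 0.42 for NRF2 targets. At LA 8h they were 0.9 for respiratory chain and mitochondrially encoded transcripts. At LA 16h they were 0.54 for inflammatory mediators, tissue repair and glycolysis, 0.81 for interferon-stimulated genes, respiratory chain and mitochondrially encoded transcripts, 0.46 for hypoxia and 0.37 for immediate early genes. At LA 24h they were 0.072 for inflammatory mediators and hypoxia, 0.11 for glycolysis and immediate early genes, and 0.61 for cholesterol synthesis, MHC class II, the integrated stress response, NRF2 targets and mitochondrially encoded transcripts. For LA effect 24h vs 8h they were 0.49 for inflammatory mediators, glycolysis, MHC class II, immediate early genes and mitochondrially encoded transcripts, 0.44 for tissue repair and hypoxia, and 0.53 for interferon-stimulated genes, respiratory chain, cholesterol synthesis and NRF2 targets. With the length trend removed LXR targets at 4 h gave 0.05, and for the difference inflammatory mediators gave 0.13 and MHC class II 0.11; the cause was not tested. Fry tests against no change rather than against other genes, so it is no check of these calls; it kept all 55 and also called lists that camera did not.

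Peak classes changed as follows, and the cause was not tested. H3K18la in both states gave adjusted p = 0.022 at 4 h with a -log10 q of at least 5, and 0.05 at 16 h and 0.056 at 24 h with a window of 1 kb. With an estimated correlation H3K18ac in both states gave 0.039 at 16 h and 0.025 at 24 h (0.041 at 24 h with the length trend removed), and H3K18ac M0 only gave 0.1 at 4 h and 0.2 at LA 24h. H3K18la M1 only gave 0.18 at LA 16h with a -log10 q of at least 5, and with an estimated correlation 0.27 at LA 16h and 0.099 at LA 24h. H3K18la M0 only gave 0.091 at LA 24h with an estimated correlation. M1-only H3K18la genes without an M1-only H3K18ac peak gave 0.082 at LA 16h with a window of 5 kb, 0.35 with a -log10 q of at least 5, and with an estimated correlation 0.27 at LA 16h and 0.091 at LA 24h.

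Shares of peaks moved with at least 50% covered, with a -log10 q of at least 5, and with equal numbers, in that order; the cause was not tested. They were 43.1, 47.2 and 69.5% for M0 H3K18la in M1, 68.4, 88.3 and 70.1% for M1 H3K18la in M0, 65.8 and 70.5% for M0 H3K18ac in M1, and 56.6, 79.1 and 71.1% for M1 H3K18ac in M0. Between marks they were 98.0, 96.0 and 92.4% for M0 H3K18la by H3K18ac, 25.9, 69.2 and 80.3% for M0 H3K18ac by H3K18la, 91.6, 99.1 and 86.0% for M1 H3K18la by H3K18ac, and 11.3, 43.6 and 69.7% for M1 H3K18ac by H3K18la.

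Reversed were Tnf for LA effect 24h vs 8h with the length trend removed (-0.01) and also without both libraries that stood apart (-0.05), Vegfa for 16h vs 0h (-0.21) and Actb for 24h vs 0h (-0.32) scaled to the reads in listed genes, and the Pearson r of LA 8h vs 8h with LA 24h vs 24h with the length trend removed (0.09); the cause was not tested.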

Other observations

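The tests of gene lists against peak classes were chosen only after the data were seen. Of 28 inflammatory mediators, 7 had an H3K18la peak in M1 and in M0 none (against 1.4% of other genes; odds ratio 24.01, Fisher adjusted p = 9.1e-06): Nos2, Cxcl10, Cxcl11, Ccl5, Cd86, Csf2 and Csf3. Of 6 MHC class II genes, H2-Ab1 and H2-Eb1 did (odds ratio 34.74, adjusted p = 0.045). Of 30 cell cycle genes, 16 had an H3K18la peak in M0 alone (53.3% against 15.9%, odds ratio 6.05, adjusted p = 0.00012) and 7 an H3K18ac peak in M0 alone (23.3% against 3.3%, odds ratio 8.89, adjusted p = 0.0015). Of 21 cholesterol synthesis genes, 10 had an H3K18la peak in M0 alone (47.6%, odds ratio 4.80, adjusted p = 0.013) and 5 an H3K18ac peak in M0 alone (23.8%, odds ratio 9.08, adjusted p = 0.013). Of 92 such tests over 23 lists, 6 passed. An H3K18la peak in M0 alone may reflect the lower fold enrichment of the M1 library (4.49 against 6.78 at shared sites) rather than a loss of the mark. The peaks come from 1 library per mark and state.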
